A study of Mus musculus with 6 samples.

How the data were processed

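RNA from whole pituitaries of 6 female mice, 3 Jmjd2a (Kdm4a) null and 3 wild-type littermates, was hybridised to one-colour Agilent arrays after Cy3 labelling, per the labels. Per the file headers the arrays sat on 1 slide read in 1 scan, and Agilent Feature Extraction 11.0.1.1 wrote the spot values. The deposited spot files hold intensity values (gProcessedSignal), which that program had background-subtracted and detrended but not normalized between arrays, along with median spot brightness and flags for spot quality. The authors' value table holds log2 values of 29154 spots for 26625 probes. Its spots were matched by their feature number, and each column correlated across spots at 0.997 or more with the log2 median spot brightness of the same array. The columns have medians of 8.25 to 8.26. The submitters' processing notes name limma without a version, and the normalization and filter they used are not given in the sources used here. The files hold no mean spot brightness, so median spot brightness was used for normexp.

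Control spots and spots marked as outliers were left out, spots of the same probe were averaged as log2(gProcessedSignal), and each array's 75th percentile was subtracted. Probes well above background on at least 3 arrays were kept (36739 of 55681). Where a gene had several, the probe with the highest mean over all arrays was used. The mouse annotation of GRCm38.p6 served only for gene symbols and the order of neighbouring genes, and 27656 of the 55681 probes matched 20972 symbols. Of the 26887 genes and features tested, 16461 had a symbol and 10426 did not. KO was compared with WT in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, two-sided) and data.table (version 1.17.8), with Benjamini-Hochberg adjustment and calls at an adjusted p under 0.05. The probes of Kdm4a were also compared by an exact two-sided permutation test over the 10 splits of the arrays.

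The 41 gene lists and cell type marker lists, the tests of the comparison between KO and WT, the rule for naming genes and the alternatives, except the restriction to features with a RefSeq symbol, were chosen before the data were examined. The closing section names the tests of explanations that were chosen later. Lists with at least 3 tested genes were compared with all other genes by limma's camera with a preset inter-gene correlation of 0.01, adjusted over the lists. With an estimated correlation 0 lists were called. Limma's fry, which asks whether a list's genes move on balance one way without comparing them with other genes, called 0 lists, had 10 at an unadjusted p under 0.05, and called 13 for change in either direction. The named genes were Kdm4a and its family, called genes without overlap between groups (up to 15 per direction), then, where fewer than 10 were found in a direction, those with the smallest p, no overlap and an absolute log2 fold change of at least 0.5, given as values. The rule also took the pituitary hormones with Gnrhr and Esr1, up to 3 members with the smallest p of each list described, and called genes within 5 Mb of Kdm4a. Where a group was not well above background on any array, the fold is given as a bound ("at least N-fold").

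The alternatives were normexp background correction with an offset of 50, quantile normalization, median centring, the authors' value table, no filter on dim probes, a filter asking for all arrays, the mean of a gene's probes, each probe alone, a variance trend with robust fitting, array weights, blocks for replicate number and for slide row, slide row 1 alone, other thresholds, and leaving out each array. A restriction to features with a RefSeq symbol was added after seeing the data. The ranges of log2 fold changes over 21 alternatives also take in slide row 2 alone. That row held 1 array per group, KO replicate 2 and WT replicate 2, and gave no test. Where an end of a range came from it, that end reflects a single pair of animals and not the processing. The steps were tested on simulated data with changes planted in values of this spread, drawn independently for each gene, in 10 runs. Of genes changed by a log2 of 1, 39.2% were recovered at an adjusted p under 0.05, against 0.8% at 0.5, 83.8% at 2 and 90.8% at 3, with 54 false calls over all runs and 0 calls where nothing was changed. A list of 21 genes shifted by 0.5 was called by camera in 10 of 10 runs, with 3 calls among 400 tests of other lists. Limma's fry called the shifted list in 3 of 10 runs. Since the genes were drawn independently, these runs do not show how often camera calls lists falsely where genes vary together.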

Results

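Pituitary gene expression was measured on 6 one-colour Agilent arrays, 3 from females lacking Jmjd2a (KO) and 3 from wild-type littermates (WT), each array from a separate animal. Jmjd2a, now named Kdm4a, encodes a histone demethylase that removes methyl groups from lysines of histone H3. The virgin mice were 8 weeks old and on a C57BL6 background. The glands were taken 24 h after activation of oestrus by soiled bedding from a stud male (the Whitten effect). Between 34634 probes (KO replicate 2) and 40567 probes (WT replicate 2) of the 55681 on an array lay well above background, and the 75th percentile of the spot signal ran from 171 to 313 intensity units. The precision of every value below is limited by this number of arrays. Across genes, which are not independent replicates, pairs of KO arrays correlated at 0.993, and pairs of WT arrays at 0.983 to 0.986. A KO array and a WT array correlated at 0.984 to 0.989, so WT arrays were as close to KO arrays as to each other. The median standard deviation of a gene was 0.23 (log2) among WT arrays and 0.15 among KO arrays. All log2 fold changes below are KO over WT, with their standard error from limma and n = 3 arrays per group.

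The targeted gene gave a lower but clearly measurable signal in the KO pituitaries. The brighter of its 2 probes read 1.96 ± 0.15 (SD, n = 3) in WT and 1.34 ± 0.13 (SD, n = 3) in KO, in log2 units relative to the array's 75th percentile. The KO signal was thus 64.9% of the WT signal (95% interval 51.8% to 81.4%), a log2 fold change of -0.62 ± 0.14. The groups did not overlap, and the exact two-sided permutation test gave p = 0.1, the smallest that 3 arrays against 3 allow, while the adjusted p over all genes was 0.237. The other probe was well above background on only 2 of the 6 arrays and read -5.06 ± 0.71 (SD, n = 3) in WT and -4.97 ± 0.42 (SD, n = 3) in KO (exact permutation p = 0.9). The part of the gene that was deleted is not given in the sources used here, and a probe outside it checks nothing, so the residual signal does not test the arrays' labels. Among the related demethylases, Kdm4b had a log2 fold change of 0.12 ± 0.12, Kdm4c of -0.02 ± 0.15 (sign kept in 16 of 21 alternatives) and Kdm4d, well above background on 2 arrays of each group, of -0.69 ± 0.29 (-0.25 with normexp), with adjusted p of 0.644, 0.958 and 0.389 in that order. Of the 117 tested genes within 5 Mb of Kdm4a, limma called 0, with 16 at an unadjusted p under 0.05 and a lowest adjusted p of 0.224. The share at an unadjusted p under 0.05 was similar over all genes and features tested (3445 of 26887).

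The comparison of KO with WT asked which pituitary transcripts depend on this demethylase shortly after oestrus induction. The clearest separations were in stress and immediate early genes and in a few others. The heat shock genes Hspa1a, Hsph1 and Dnaja1, which encode a chaperone and co-chaperones, had log2 fold changes of 2.11 ± 0.23, 1.47 ± 0.16 and 1.20 ± 0.14 (adjusted p = 0.0932, 0.0932 and 0.0984). On the lower side stood Rps4l, a relative of a ribosomal protein gene, at -3.66 ± 0.31, and the immediate early gene Ier2 at -1.81 ± 0.15 (adjusted p = 0.0774 for both). Dnajb3, another co-chaperone gene, read -1.97 ± 0.20, Csf2ra, a subunit of the GM-CSF receptor, -1.25 ± 0.12, Klhl35 -1.13 ± 0.12 and Akr1c13, an aldo-keto reductase, -1.45 ± 0.16, each with an adjusted p of 0.0932. The rule that named these genes required no overlap between the 3 KO and the 3 WT arrays, so their separation is not a further result. Of all genes and features tested, 20.6% met that condition. Hspa1a and Rps4l each have a near-identical relative (Hspa1b and Rps4x), so which copy their probes measured is uncertain. The sizes depended on the background treatment: normexp gave 1.11 for Hspa1a, -1.21 for Dnajb3, -0.67 for Klhl35 and -0.71 for Akr1c13, and the authors' value table gave 1.18, -1.16, -0.56 and -0.59 in that order.

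The same selection by smallest p took in further genes whose groups did not overlap. On the higher side these were Ppp1r3c, a glycogen-targeting subunit of a phosphatase (1.25 ± 0.16), Doc2b (1.54 ± 0.22), Fstl5 (1.23 ± 0.18), Gckr (1.13 ± 0.16) and Arglu1 (0.88 ± 0.12), with adjusted p from 0.123 to 0.166. On the lower side were Dusp1, a phosphatase of MAP kinases (-2.31 ± 0.29), C2cd4a (-1.15 ± 0.14) and Nkx3-2 (-1.28 ± 0.15), with adjusted p from 0.111 to 0.123. Hsd17b2, which encodes a steroid dehydrogenase, was not well above background on any KO array and, with the processing used here, at least 2.40-fold lower there (adjusted p = 0.123), while normexp gave a log2 fold change of -0.40. Normexp also gave smaller values for Gckr (0.22, and 0.39 in the authors' value table), Doc2b (0.74 and 0.83), Nkx3-2 (-0.40) and Ppp1r3c (0.80).

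By limma with Benjamini-Hochberg adjustment, 0 of the 26887 genes and unnamed features tested passed an adjusted p under 0.05, and 15 had an adjusted p under 0.1, of which 5 were higher and 10 lower in KO. At an unadjusted p under 0.05 there were 3445, where 1344 would be expected by chance, 1046 of them higher and 2399 (69.6%) lower. The lower share was 56.7% with median centring, 46.8% in the authors' value table and 43.2% with quantile normalization, so the balance of directions depended on the scaling. The median log2 fold change of all genes and features tested was -0.076. A value below 0 thus need not lie below that of the other genes. The 3 KO and 3 WT values did not overlap for 5549 genes (20.6%, against 10% by chance). Normexp background correction called 24 genes, a variance trend with robust fitting called 27, the authors' value table gave 27, and 17 features were called by all 3 of these. Of those 17, 13 had a symbol, and among them, chosen after their values were seen, were Hspa1a, Hsph1, Dnaja1, Arglu1 and Chordc1, all higher in KO, and Ier2, Rps4l, Csf2ra, Dnajb3, C2cd4a, Dusp1 and Alox12e, all lower. The count at an unadjusted p under 0.05 was 5508 without WT replicate 2, 2160 without KO replicate 2 and 1969 without KO replicate 3, and without WT replicate 1 the single gene Junb was called (log2 fold change -2.57 ± 0.12, adjusted p = 0.03).

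**Figure D1:**
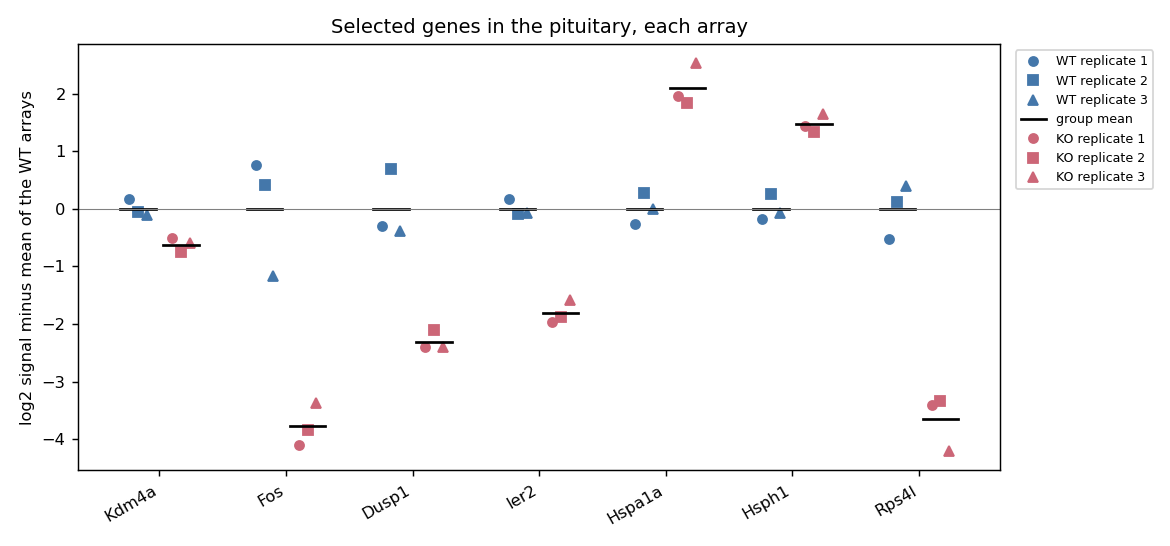
Log2 signal of 7 genes on each of the 6 arrays, minus the mean of the 3 WT arrays (vertical axis), by gene (horizontal axis), with blue points for WT, red points for KO, a marker shape for each replicate number and black bars for group means. The 3 KO arrays lie apart from the 3 WT arrays for every gene drawn, with Kdm4a at a mean difference of -0.62 and Fos at -3.77. For Dusp1, Ier2, Hspa1a, Hsph1 and Rps4l this separation was required by the rule that named them.

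Immediate early genes, which are transcribed within minutes of a stimulus, were lower in KO as a list. Fos had a log2 fold change of -3.77 ± 0.49, Ier2 of -1.81 ± 0.15, Dusp1 of -2.31 ± 0.29 and Junb of -2.00 ± 0.45. Of the 14 members tested, 8 were lower when adjusted over the list alone and 0 over all genes. The list's median was -0.83, and camera called it lower (adjusted p = 0.00119), with adjusted p = 0.687 with an estimated correlation. Other members had values above 0 with wide errors, as Nr4a1 (0.61 ± 1.25) and Nr4a2 (1.25 ± 1.08), which like Junb were named after their values were seen. WT replicate 1 had a list mean of -0.62, at the level of the KO arrays (-0.60 to -0.19), while the other WT arrays read 0.87 and 1.04.

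The heat shock list was higher in KO through 3 of its 8 tested members. Hspa1a, Hsph1 and Dnajb1 (1.23 ± 0.21) passed when adjusted over the list alone and 0 did so over all genes, while Hspa8 read -0.12 ± 0.20 and Hsp90aa1 0.22 ± 0.15, both named after their values were seen. Camera called the list higher (median 0.16, adjusted p = 0.00111), with adjusted p = 0.492 with an estimated correlation. The call was lost within the upper slide row alone (adjusted p = 0.0543, the highest over 19 alternatives, whose lowest was 5.06e-06). Glucocorticoid-responsive genes were also higher as a list, with all 10 members above 0 and a median of 0.35 (camera adjusted p = 1.01e-05; adjusted p = 0.492 with an estimated correlation). Klf9 had a log2 fold change of 0.56 ± 0.13, the only member to pass when adjusted over the list alone, followed by Fkbp5, a co-chaperone of the glucocorticoid receptor, at 0.38 ± 0.13 and the clock gene Per1 at 0.93 ± 0.33 (0.61 to 1.5025 over 21 alternatives). The 1.5025 of Per1 came from slide row 2 alone, with 1 array per group.

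Genes of cell division were lower in KO. Top2a, Birc5 and Ccnb2, which act in chromosome segregation and mitotic entry, had log2 fold changes of -2.59 ± 0.70, -2.49 ± 0.63 and -1.60 ± 0.39. All 21 cell cycle members tested were below 0, and 8 passed when adjusted over the list alone, against 0 over all genes. The list's median was -0.81 (camera adjusted p = 1.42e-06; adjusted p = 0.687 with an estimated correlation). WT replicate 3 stood highest, with a list mean of 1.41 against 0.09 and 0.16 on the other WT arrays and -0.76 to -0.44 on the KO arrays. Without it the list's median was -0.40, and Top2a read -1.76 ± 0.37 (with all arrays, -0.998 with normexp and -0.822 in the authors' value table), Birc5 -1.74 ± 0.34 and Ccnb2 -1.13 ± 0.20. The same array carried the neutrophil and Schwann cell transcripts described with the cell type markers.

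Cholesterol biosynthesis genes were lower in KO as a list. Insig1, a regulator of sterol synthesis, and Idi1, an enzyme of the pathway, had log2 fold changes of -0.67 ± 0.14 (-0.80 to -0.41 over 21 alternatives) and -0.67 ± 0.13. Of the 17 members, 16 were below 0, and 5 passed when adjusted over the list alone, against 0 over all genes (median -0.30; camera adjusted p = 2.3e-04; adjusted p = 0.687 with an estimated correlation).

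Ribosomal protein genes and genes of oxidative phosphorylation were lower in KO by small amounts. All 33 ribosomal protein genes tested were below 0, with a median of -0.31 (camera adjusted p = 1.42e-06; adjusted p = 0.702 with an estimated correlation), as in Rps3 (-0.64 ± 0.20), Rps2 (-0.54 ± 0.18) and Rps19 (-0.45 ± 0.13). The other probe of Rps3 read -0.13 ± 0.15, and that of Rps2 -0.55 ± 0.16. Over 21 alternatives Rps3 ran from -0.95 to -0.02, Rps2 from -0.76 to -0.11 and Rps19 from -0.56 to -0.22. The -0.02 of Rps3 and the -0.11 of Rps2 came from slide row 2 alone, with 1 array per group. The list's call was lost with quantile normalization (adjusted p = 0.392) and in the authors' value table (0.154), within a range over 19 alternatives of 6.42e-12 to 0.392. Of the 32 oxidative phosphorylation genes 31 were below 0, among them Uqcrfs1 (-0.31 ± 0.11, from -0.36 to -0.15 over 21 alternatives) and Ndufb9 (-0.37 ± 0.14, from -0.52 to -0.06), with a median of -0.26 (camera adjusted p = 2.3e-04; adjusted p = 0.702 with an estimated correlation). Without WT replicate 3 the distance of this median from that of all genes went from -0.18 to -0.09 and the call was lost (adjusted p = 0.104, the highest over 19 alternatives, whose lowest was 1.31e-05). The -0.06 of Ndufb9 came from slide row 2 alone. In neither list did any member pass when adjusted over the list alone or over all genes. Below the median of all genes lay 33 of the 33 ribosomal protein genes and 28 of the 32 oxidative phosphorylation genes.

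Hypoxia-responsive genes were lower as a list (11 of 12 below 0, median -0.29; camera adjusted p = 0.0409, and adjusted p = 0.492 with an estimated correlation), with Slc2a1, a glucose transporter, at -0.31 ± 0.11, Ndrg1 at -0.40 ± 0.15 and Adm at -0.40 ± 0.15. Genes of secretory granules and exocytosis were higher (11 of 14 above 0, median 0.13; camera adjusted p = 0.0314, and adjusted p = 0.492 with an estimated correlation), led by Pcsk1n at 0.47 ± 0.11 and Scg5 at 0.34 ± 0.12, while the syntaxin gene Stx1a read -0.50 ± 0.14. Steroid receptors and their coregulators were higher (8 of 12 above 0, median 0.16; camera adjusted p = 0.0314, and adjusted p = 0.492 with an estimated correlation), with the oestrogen receptor gene Esr1 at 0.31 ± 0.13. The 3 probes of the corepressor gene Ncor1 went both ways, at 0.60 ± 0.20 for the brightest, 0.60 ± 0.18 and -0.43 ± 0.12. Over 21 alternatives Adm ran from -0.58 to -0.06, Ndrg1 from -0.52 to -0.28, Pcsk1n from 0.44 to 0.72, Scg5 from 0.27 to 0.61, Stx1a from -0.60 to -0.21 and Esr1 from 0.09 to 0.41. In these 3 lists 0 members passed when adjusted over the list alone or over all genes. Against the median of all genes, 10 of 12 hypoxia genes lay below, and 12 of 14 secretory granule genes and 10 of 12 steroid receptor and coregulator genes lay above. Without WT replicate 3 the adjusted p was 0.202 for hypoxia and 0.104 for secretory granules. The hypoxia call held in 10 of 19 alternatives, the steroid receptor call in 10 and the secretory granule call in 15.

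**Figure D2:**
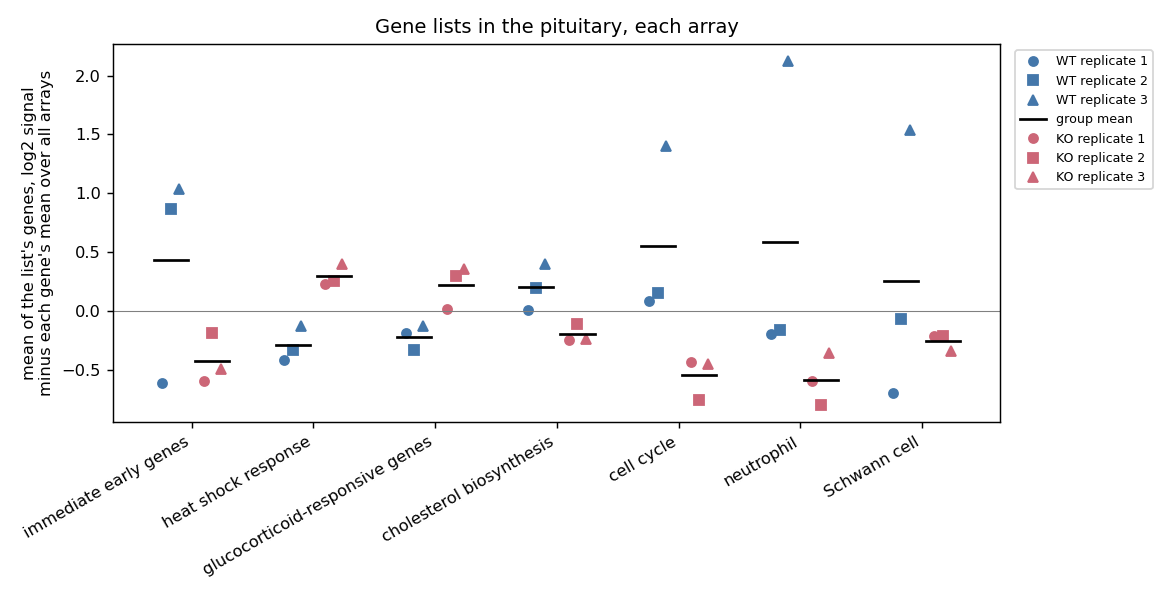
Mean of the genes of 7 lists on each of the 6 arrays (vertical axis, log2 signal minus each gene's mean over all arrays), by list (horizontal axis), with blue points for WT, red points for KO, a marker shape for each replicate number and black bars for group means. WT replicate 1 lies at -0.62 among the immediate early genes, and WT replicate 3 lies at 1.41, 2.12 and 1.54 for the cell cycle, neutrophil and Schwann cell lists.

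The pituitary hormone genes were not separated from their replicate error. Log2 fold changes were -0.26 ± 0.22 for Prl, -0.22 ± 0.23 for Gh, -0.23 ± 0.22 for Pomc, -0.26 ± 0.21 for the shared glycoprotein subunit Cga, 0.03 ± 0.19 for Lhb, 0.14 ± 0.14 for Tshb and 0.41 ± 0.86 for Fshb, with adjusted p from 0.590 to 0.955. The signs of Prl, Gh, Pomc and Cga turned in the authors' table (0.08, 0.13, 0.09 and 0.04). Over 21 alternatives Fshb ran from -2.02 to 1.62, with its sign kept in 19 (-0.32 without WT replicate 1), and Lhb from -0.17 to 0.42, with its sign kept in 18, while Tshb ran from 0.06 to 0.36. The -2.02 of Fshb and the 0.42 of Lhb came from slide row 2 alone, with 1 array per group. Fshb spanned 11.2-fold among the 3 WT arrays. The receptor for gonadotropin-releasing hormone, Gnrhr, had a value of -0.28 ± 0.18 (adjusted p = 0.526; -0.43 to -0.11 over 21 alternatives). Camera found no shift of the hormone list (adjusted p = 0.972), of the list for activin, inhibin and GnRH control (0.972), of oestrogen-responsive genes (0.913), of pituitary transcription factors (0.913) or of receptors for hypothalamic signals (0.976). For 3 of these the median, the mean and camera's direction differed in sign: the activin list (median 0.01, mean -0.13, up), oestrogen-responsive genes (median -0.08, mean 0.06, up) and transcription factors (median -0.02, mean -0.04, up). Camera's direction is relative to the other genes and not to 0, and the median of all genes was -0.076.

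Among regulators of histone H3 lysine methylation other than Kdm4a, 11 of 20 members were above 0 (median 0.02, mean -0.01; camera adjusted p = 0.303, direction up). Setd2, Nsd1 and Phf8, a methyltransferase pair and a demethylase, had values of 0.45 ± 0.16, 0.33 ± 0.13 and 0.38 ± 0.12 by their brightest probes, and 0 members passed when adjusted over the list alone or over all genes. The other probe of Nsd1 read -0.02 ± 0.18, and the other probes of Phf8 read 0.13 ± 0.17 and -0.04 ± 0.48. Over 21 alternatives Setd2 ran from 0.09 to 0.63, Nsd1 from 0.15 to 0.40 and Phf8 from 0.16 to 0.43. The 0.09 of Setd2 came from slide row 2 alone. Imprinted genes (adjusted p = 0.284), germline genes (0.397), antigen presentation (0.439), interferon response (0.584; median 0.01, mean -0.02, direction up) and the unfolded protein response (0.776) were not called either. Cdkn1c, an imprinted inhibitor of cell division, had a log2 fold change of -0.56 ± 0.18 (adjusted p = 0.333).

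None of the 19 cell type marker lists was called by camera. Markers of corticotropes, the cells that make ACTH, came closest (adjusted p = 0.0509; adjusted p = 0.642 with an estimated correlation): the vasopressin receptor gene Avpr1b (-0.58 ± 0.11) and the CRH receptor gene Crhr1 (-0.52 ± 0.16) were lower when adjusted over the list alone, 2 of 4 members, while Tbx19 read -0.16 ± 0.15 and Pomc is given above. Over 21 alternatives Crhr1 ran from -0.79 to -0.39 and Tbx19 from -0.25 to -0.03. The corticotrope list was called in 9 of 19 alternatives (adjusted p 0.0292 to 0.145) and the neutrophil list in 11. Neutrophil markers came next (7 of 7 below 0, median -1.10; adjusted p = 0.0659; adjusted p = 0.702 with an estimated correlation), with S100a8 at -1.79 ± 0.79 (-2.44 to -0.75 over 21 alternatives, the latter from slide row 2 alone) and S100a9 at -1.68 ± 0.75 (-2.23 to -0.74). WT replicate 3 carried most of this signal: its neutrophil list mean was 2.12, against -0.20 and -0.16 on the other WT arrays, and without it the list's adjusted p was 0.247, the highest over 19 alternatives, whose lowest was 0.0131. Its Schwann cell list mean was 1.54, against -0.70 and -0.07. Fibroblast and pericyte markers had an adjusted p of 0.180, with Col1a1, a collagen gene, at -0.83 ± 0.23. The remaining 16 marker lists had adjusted p of 0.303 or more. Among these, camera's direction (up) differed in sign from the median or mean for skeletal muscle (median -0.08, mean 0.01), hypothalamic neurons (0.03 and -0.23) and stem and folliculostellate cells (-0.08 and -0.09).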

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

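The restriction to features with a RefSeq symbol was the only alternative chosen after the results were seen. The count of called genes (0) became 24 with normexp background correction, 27 in the authors' value table, 27 with a variance trend and robust fitting, 11 with probes well above background on all arrays, 4 with only features with a RefSeq symbol, 15 at an adjusted p under 0.1 and 3445 at an unadjusted p under 0.05. Fewer features were tested in the authors' table (20832), with the stricter filter (24309) and with RefSeq symbols only (16461). The number tested does not alone account for the 27 calls in the authors' table, since the smaller RefSeq set gave 4. The values in that table also differ from those used here. For the authors' table, normexp and the variance trend the cause was not tested. Without single arrays the count ran from 0 to 1. It was 0 with quantile normalization, median centring, no filter, the mean of probes, each probe alone, array weights, the slide row as a block and slide row 1 alone. The Kdm4a log2 fold change kept its direction throughout, from -0.70 to -0.50, with -0.59 within slide row 1 and -0.70 within slide row 2 (1 array each, no test). The 10 shifted lists became 0 with an estimated correlation, 0 with fry and 6 within slide row 1, where fewer arrays were used, and ran from 7 to 11 without single arrays. The estimated correlation took the place of the preset one in the same camera test, so all 10 calls depended on the preset value. For fry the cause was not tested. With the replicate block, 0 genes and 11 lists were called and the adjusted p of Kdm4a was 0.429. Arrays of the same number correlated at 0.15, -0.18 and -0.08 in their deviations from their group means, and 1 of 3 KO arrays correlated best with its own number. Of the fold changes of named genes under alternatives, 2803 stayed as reported, 99 moved and 55 passed the threshold. Between 62.2% and 72.9% of probes were well above background, so transcripts below that level were not measured.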

Other observations

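The tests of scaling, of cells of another type on WT replicate 3 and of the splits for the count of called genes were chosen after the results were seen.

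Several transcripts differed widely among the WT animals. Gal, which encodes the neuropeptide galanin, spanned 16.5-fold among the 3 WT arrays and 1.20-fold among the KO arrays. The nuclear receptor gene Nr4a1 spanned 37.1-fold and 2.40-fold, and Fshb 11.2-fold and 2.35-fold. These genes were chosen after their values were seen. Across all genes tested, 18736 (69.7%) had a larger standard deviation in WT. The circadian clock list was not called (16 genes, median 0.26, camera adjusted p = 0.151; adjusted p = 0.687 with an estimated correlation), with Per1 at 0.93 ± 0.33 (0.61 to 1.5025 over 21 alternatives, the latter from slide row 2 alone) and Bhlhe41 at -0.76 ± 0.19 (-0.90 to -0.20, with its other probe at -0.37 ± 0.20).

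The lower immediate early genes and higher heat shock genes in KO kept their directions under all 5 scalings, with a highest camera adjusted p of 0.00174. A constant per array moves a list and the other genes alike, so median centring could not have turned a direction. Normexp, quantile normalization and the authors' value table could have, and for these the result argues against scaling as the cause. Leaving out each array in turn, the smaller distance of either list's median from that of all genes stayed at 0.148 or more, which argues against a single deviating array. Handling before freezing cannot be told apart from genotype, since the order of handling is not given in the sources used here. The mean of the immediate early genes differed by up to 1.66 between arrays of the same group, against -0.86 between groups. An effect of the genotype stays open and was not tested separately.

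For the lower cell cycle, cholesterol, oxidative phosphorylation and ribosomal protein lists, 10000 random lists matched on mean signal were drawn. The medians of the cell cycle and cholesterol lists lay at percentile 0.010, the smallest the draws can give. This argues against a shift shared by genes of that signal level. Oxidative phosphorylation lay at 0.17, but its matched random lists had a median of -0.15, against -0.26 for the list. For that list a shared shift is thus argued against only as the whole cause, and may account for part of the size. Ribosomal proteins lay at percentile 3.02, so such a shift may account for their lower values. Without WT replicate 3, whose array carried neutrophil and Schwann cell transcripts, the cell cycle list was still lower (camera adjusted p = 5.94e-06, range over alternatives 6.18e-09 to 2.50e-05), with its distance from the median of all genes at -0.32 instead of -0.74. Cells of another type on that array are thus argued against as the whole cause, and a part of the size may come from them.

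A chromosome segment of another strain may differ between the groups around Kdm4a or Rps4l. The 50 tested neighbours of Kdm4a had a mean absolute statistic that a share of 0.397 of random windows reached, and the 33 of Rps4l one that a share of 0.324 reached. As few genes of such a segment need differ, it cannot be told apart from other causes for either gene.

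The 6 arrays allow 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 0 called genes (highest other 0; 10 splits gave as many), 3445 genes at an unadjusted p under 0.05 (highest other 2175; 1 split) and 10 called lists (highest other 11; 3 splits).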
